A study of Mus musculus with 45 samples.

How the data were processed

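RNA from lung sections of 45 samples was measured on dual-colour Agilent mouse arrays, with lung RNA in Cy5 and a pooled mouse reference RNA in Cy3 and 200 ng of RNA per array per the labels. Per the file headers, the authors' scans were read with Agilent Feature Extraction 11.0.1.1 with linear and lowess dye normalisation. The deposited scanner files hold the median signal and the median local background of each spot in intensity units for each dye, and flags coded 0 or 1 for spots well above background, uneven, outlying or saturated. The deposited scanner files also hold the software's own log ratio of Cy5 to Cy3 as log10. The deposited table of normalised values is in log2, with array medians between -0.0364 and -0.00572. Its slope against loess log ratios computed here without background subtraction was 1 on 40 of the 45 arrays. The 5 others lay on the same slide, 4 at 0.904 to 0.974 and replicate 1 of NRCWE-049 at 54 µg at 0.666 with a correlation of 0.785. The scanner files hold no mean signal, so the median signal was used where the plan had named the mean.

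Arrays were processed with R 4.3.3, limma 3.58.1 and the package data.table in version 1.17.8, and figures were drawn with matplotlib 3.10.9. Background was corrected by normexp with an offset of 50, and log2 ratios of Cy5 to Cy3 were normalised by loess within each array with control spots at weight 0. Spots that the software marked uneven or outlying, 237 to 357 per array, were left out, repeated spots of a probe were averaged, and no spot was saturated. Of 55,681 probes that are not controls, 31,617 were well above background in Cy5 on at least 4 of the 5 arrays of at least 1 group and were kept. Of several probes of a gene the brightest stood for it, which left 23,698 genes or transcripts, and 5522 of them had more than 1 probe. Symbols were assigned through the transcript accessions of the array, which named 27,235 probes and 20,660 genes. A genome sequence was not used here, so probe positions are not given.

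Groups followed the sample titles, which match the description field, and replicates are numbered in the order of the sample numbers. The treatment field named another group on 23 arrays, and the field for the time point holds the strain. The design text speaks of 4 doses and names 18 and 54 µg, and no other dose was found in the labels. Slides and scan order came from the file headers. The share of probes well above background describes the signal of an array, and the number of arrays limits the precision. A high share is no sign of a good array. Replicate 1 of NRCWE-049 at 54 µg, with 83.3%, had the lowest mean correlation with the other arrays, 0.822. The p values measure the spread between samples, and the labels leave open whether sections of a group came from separate mice.

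A single limma fit with a mean for each of the 9 groups gave all comparisons, with 36 residual and 3.93 prior degrees of freedom, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Differences between the 4 materials at a dose were tested with limma's moderated F test, and the 6 pairs at each dose are given as detail. The named genes were chosen by rule. Against control at 54 µg they were the 12 that rose and the 8 that fell the most, with an adjusted p below 0.05 and the same direction in all 5 arrays, and at 18 µg the 6 that rose and the 4 that fell the most. Between doses or materials they were the 5 with the largest change or, for the F test, the largest range, and where fewer than 3 genes passed, the 3 with the smallest p, given as values. From each list the rule took up to 4 members with the smallest p, and features without a gene symbol were passed over. Genes not above background on any array of a group were given a lower bound, the fold against the level at which probes stop being well above background. The groups, comparisons, tests, lists, naming rule and most of the alternatives were fixed before the data were examined.

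The 27 lists were acute phase proteins, chemokines, inflammatory cytokines and inflammasome, alternatively activated macrophage genes, particle-laden macrophage and lysosome genes, extracellular matrix and fibrosis, complement, Nrf2 and oxidative stress, p53 and DNA damage, cell cycle, interferon response, cholesterol synthesis, antigen presentation by MHC class II and circadian clock. The others were markers of neutrophils, of alveolar macrophages and monocytes, of B cells and plasma cells, of T cells and NK cells, of mast cells, basophils and eosinophils, of alveolar type 2 cells, of alveolar type 1 cells, of airway club, goblet and ciliated cells, of endothelial and lymphatic cells, of heart and skeletal muscle, of fat cells, of red blood cells and of thymocytes. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Members were also counted after adjusting over the list alone.

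Alternatives left out the background subtraction, took the software's log ratio, Cy5 alone or the deposited log2 values, dropped the filter, averaged probes, fitted slide as a fixed or random block, left out the pair of slides scanned last, the 23 arrays with conflicting labels or each array in turn, asked for a 1.5-fold change, or fitted only the groups compared. Added after the data were seen were fits without the 4 arrays with over 75% of probes above background, with that share as a covariate, without replicate 1 of NRCWE-049 at 54 µg, and with 3 scores of other tissue. For splits, the arrays of the groups compared were regrouped 100 times, the real grouping included, with a fixed seed. The method was tested on simulated data with changed genes added. Values were drawn for each gene apart from a normal distribution, with no correlation between genes, no slide effect and no outlying array. In that setting the method recovered 72% of genes changed 1.5-fold, 100% of those changed 2-fold or 3-fold and 98% of those changed 4-fold, with 11 false calls among 23,698 genes and 0 in an unchanged comparison. These rates do not carry over to the real arrays, which lack that simple setting.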

Results

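Gene expression in the lung was measured 28 days after a single instillation of carbon nanotubes (CNT) into the trachea of female C57BL/6 mice, an inbred laboratory strain. The 4 materials are known here only by the code names NRCWE-049, NRCWE-048, NRCWE-047 and NRCWE-046, and each was given at 18 or 54 µg per animal in a volume of 40 µl. With the control group this made 9 groups of 5 arrays, 45 arrays in all. Each array compared lung RNA, labelled with the dye Cy5, with a pooled mouse reference RNA, labelled with Cy3. The labels describe the lung RNA as taken from random sections, 5 per group, and do not say in so many words that each array stands for a separate mouse. The series title asks how strongly each material disturbs pathways of lung disease, and the comparisons with control address that question for each material and dose.

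Between 44.3% and 84.1% of the lung RNA probes lay well above background on an array, and the median Cy5 signal ran from 93 to 430.5 intensity units. After filtering, 23,698 genes or unnamed transcripts were tested, of which 14,318 had a gene symbol. The number of arrays, 5 per group, limits the precision of every value. Groups follow the sample titles. A second label, the treatment field, named another group than the title on 23 of the 45 arrays. With only the 22 arrays on which both labels matched, 2 or 3 per group, limma called 1349 genes for NRCWE-049 at 54 µg, 941 higher and 408 lower, and 0 for NRCWE-049 at 18 µg and for NRCWE-048 at 54 µg, with 836 and 1581 at an unadjusted p below 0.05. The 3 arrays of NRCWE-049 at 54 µg among these 22 were all on slides without a control. The arrays lay on 9 slides, and 4 of the slides held no control array. Gene values below are log2 changes ± SE against 5 control arrays unless another group is named, and p is limma's p adjusted over all genes tested.

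**Figure D1:**
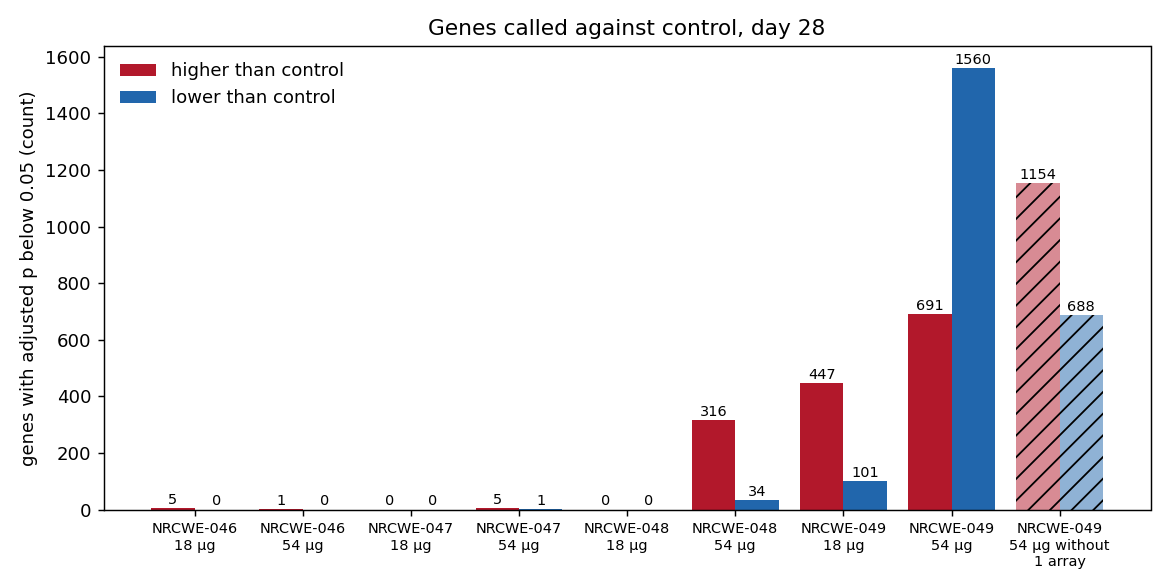
Genes with an adjusted p below 0.05 against control (vertical axis, count) for each material and dose (horizontal axis), with genes higher than control in red and lower in blue. NRCWE-049 gave 548 at 18 µg and 2251 at 54 µg, and the hatched pair of bars shows the latter without 1 array, when 1154 rose and 688 fell.

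At 54 µg of NRCWE-049, genes of acute phase proteins, chemokines and macrophages were among those higher than in control lung. Saa3, an acute phase protein gene, rose by 4.41 ± 1.04 (adjusted p 0.00822), and the chemokine genes Cxcl5, Ccl2, Ccl7 and Ccl9 rose by 3.22 ± 0.66, 2.65 ± 0.70, 2.59 ± 0.78 and 2.37 ± 0.46. Slc26a4, which encodes the anion exchanger pendrin, rose by 3.51 ± 0.73 (adjusted p 0.00412). Ly6i and Ly6f, members of the Ly6 family of surface proteins, rose by 3.50 ± 0.85 and 3.17 ± 0.78. Wfdc17 rose by 2.51 ± 0.61, Jchain, the joining chain of secreted antibody, by 2.10 ± 0.55, Oas1a, an interferon-induced antiviral gene, by 2.31 ± 0.70 and Gpnmb, a gene of lysosome-rich macrophages, by 2.07 ± 0.66. Among the genes that fell were Gsta2 and Gsta3, which encode glutathione transferases, by 1.40 ± 0.31 and 1.24 ± 0.21 (adjusted p 4.62e-04 for Gsta3), Pon1, a paraoxonase gene, by 1.38 ± 0.39, and Hlf, a clock-driven transcription factor gene, by 1.35 ± 0.27. Cst8 fell by 1.80 ± 0.37, Slc26a1, a sulfate transporter gene, by 1.5 ± 0.36, Cys1 by 1.31 ± 0.22 and Scgb1c1 by 1.26 ± 0.34. Each of these 20 genes moved the same way on all 5 arrays, which the naming rule required. Cxcl5 and Ly6f were well above background on only 2 and 3 of the 5 control arrays.

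Several of the 27 gene lists were higher at 54 µg of NRCWE-049 by camera with its preset correlation, and none was called with an estimated correlation. Of 24 measured genes of particle-laden macrophages and lysosomes, 11 rose and none fell, 16 adjusted over the list alone, with Ctsd, a lysosomal protease gene, at 1.38 ± 0.27, Plin2, a lipid droplet gene, at 0.86 ± 0.17 and Trem2, a macrophage receptor gene, at 2.04 ± 0.50. The list's median was 0.83 and its camera adjusted p 7.57e-12, against an adjusted p of 0.236 with an estimated correlation. Of 23 chemokine genes 12 rose and 1 fell (median 0.75, camera adjusted p 3.11e-08, adjusted p = 0.236 with an estimated correlation), with the same 12 and 1 adjusted over the list alone. Among 15 genes of cytokines and the inflammasome 6 rose, among them Tnf at 0.77 ± 0.22, Csf2 at 1.13 ± 0.35 and Il33 at 1.13 ± 0.32, and Tslp, an epithelial cytokine gene, fell by 0.50 ± 0.13. That list had 9 higher and 1 lower adjusted over the list alone, and its adjusted p was 0.236 with an estimated correlation. Of 16 acute phase genes 3 rose, 5 adjusted over the list alone, and of 15 complement genes 5 rose, 7 adjusted over the list alone, with Lcn2 at 2.05 ± 0.41 and C3 at 1.29 ± 0.32. The medians were 0.68 and 0.62, and the adjusted p was 0.236 for each list with an estimated correlation. B cell and plasma cell markers, with 5 of 19 rising and 9 adjusted over the list alone, and T cell and NK cell markers, with 5 of 20 rising and 6 adjusted over the list alone, had medians of 0.60 and 0.35, each with an adjusted p of 0.236 with an estimated correlation. Of 26 matrix genes 4 rose and 1 fell, 8 and 3 adjusted over the list alone, with Mmp14, a matrix protease gene, at 0.80 ± 0.17, Col3a1 and Loxl1, genes of collagen and of its cross-linking, at 0.84 ± 0.27 and 0.58 ± 0.18, and Postn, which encodes periostin, fell by 0.82 ± 0.23. The matrix list's median was 0.23 with a camera adjusted p of 0.00498 and an adjusted p of 0.239 with an estimated correlation. Only 2 slides held this group and a control, and on both the medians of the macrophage and lysosome, chemokine and acute phase lists lay above control. The medians of the cytokine, complement, matrix, B cell and T cell lists lay above it on 1 of the 2.

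Genes of the clock and of alveolar type 1 cells, the flat cells that line the air sacs, were lower at 54 µg of NRCWE-049. Of 16 clock genes 7 fell and none rose, all 7 also adjusted over the list alone, with Per1 at -1.09 ± 0.28, Cry2 at -0.61 ± 0.15 and Tef at -1.05 ± 0.27. The median was -0.45 and the camera adjusted p 0.0229, against an adjusted p of 0.236 with an estimated correlation, and fry, which tests whether a list moves 1 way, gave 0.00392. Of 10 alveolar type 1 markers 5 fell, 6 adjusted over the list alone (median -0.42, camera adjusted p 0.00247, adjusted p = 0.239 with an estimated correlation), with Clic5 at -0.78 and Cav1 at -0.67. The 20 genes of the interferon response had a median of 0.84 with 2 rising, also 2 adjusted over the list alone (camera adjusted p 9.83e-07, adjusted p = 0.364 with an estimated correlation), and lay at 0.03 and 0.05 on the 2 slides shared with a control. The 19 Nrf2 and oxidative stress genes went both ways, 2 up and 3 down, 3 and 6 adjusted over the list alone (camera adjusted p 0.92), with Gclc, a glutathione synthesis gene, at 0.73 ± 0.19 and Gpx3, a glutathione peroxidase gene, at -0.45 ± 0.12. Scgb1a1, the club cell secretoglobin gene, was at -0.81 (adjusted p 0.0172) and was the 1 airway marker of 15 to fall. Endothelial markers had a median of -0.37 with none of 11 called (camera adjusted p 0.0427, adjusted p = 0.481 with an estimated correlation), and without replicate 1 the median was -0.06 (camera adjusted p 0.521).

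In total 2251 genes were called at 54 µg of NRCWE-049, 691 higher and 1560 lower, of which 787 changed by at least 1.5-fold. Replicate 1 of this group had 83.3% of probes well above background, and in it the marker scores of endothelial and alveolar type 1 cells were -1.57 and -1.11, below the other 4 arrays. Its mean correlation with the other arrays was 0.822, the lowest of all, where the next lowest array had 0.9295. Without that array 1842 genes were called, 1154 higher and 688 lower, so the larger share changed side. The deposited normalised log ratios gave 43 genes, 27 higher and 16 lower. The count was 799 without control replicate 3, 1251 without control replicate 4, 3731 without exposed replicate 2 and 1360 without exposed replicate 4. It was 91 with only the groups compared in the fit, 53 higher and 38 lower, and 6100 without the pair of slides scanned last, which left 2 exposed arrays. Replicates 1 and 2 shared slides with controls. The other 3 arrays lay on the pair of slides scanned last, which held no control, so a slide block ties them to control only through other exposed groups. With slide as a fixed block 2235 genes were called, 326 higher and 1909 lower, with 255 of the 691 and 1073 of the 1560 among them. Without replicate 1 that block left 17 genes.

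**Figure D2:**
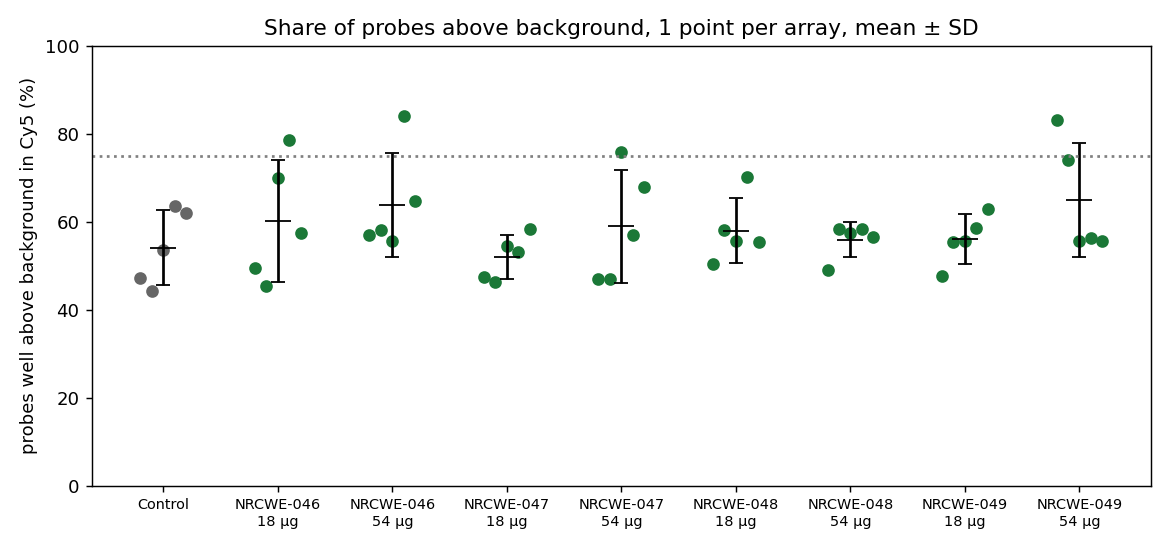
Probes well above background in the lung RNA channel (vertical axis, percent) on each array (points) by group (horizontal axis), with the mean and SD of 5 arrays per group and a dotted line at 75%. 4 arrays lie above the line, among them NRCWE-049 54 µg replicate 1 at 83.3%.

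At 18 µg of NRCWE-049, genes of the interferon response and of chemokines were among those higher than in control lung. Saa3 rose by 4.18 ± 1.04 (adjusted p 0.0266), Ly6i by 3.89 ± 0.85 and Ly6f by 3.43 ± 0.78, and the neutrophil-attracting chemokine gene Cxcl5 by 3.52 ± 0.66 (adjusted p 0.0107). Irf7, a master regulator of the interferon response, rose by 2.98 ± 0.73 and Ifi27l2a, an interferon-induced gene, by 2.99 ± 0.77. Setd5, a gene of chromatin regulation, fell by 1.06 ± 0.11 (adjusted p 2.98e-07), Rnd1, a small GTPase gene, by 1.13 ± 0.17 (adjusted p 3.60e-04), Rab5c, an endosome gene, by 1.1 ± 0.19 and Tef, a clock-driven transcription factor gene, by 1.07 ± 0.27. Of 20 interferon genes 10 rose, and all 20 were higher adjusted over the list alone (median 1.61, camera adjusted p 6.07e-22), with an adjusted p of 0.0619 with an estimated correlation. The rise was not shared evenly by the arrays. Interferon scores of single arrays ran from 0.0448 to 2.5, with controls at -0.289 to 0.304. Chemokine scores ran from 0.159 to 1.96, with controls at -0.202 to 0.286. Of 23 chemokine genes 11 rose, 17 adjusted over the list alone, and of 15 complement genes 8 rose, 10 adjusted over the list alone, with C1qa at 1.51 ± 0.35 and Cfb at 1.44 ± 0.32. The medians were 1.11 and 0.88, and the adjusted p was 0.0548 for each with an estimated correlation. Markers of B cells and plasma cells (4 of 19 rose, 18 adjusted over the list alone, median 0.91) and of T cells and NK cells (4 of 20 rose, 17 adjusted over the list alone, median 0.59) also had an adjusted p of 0.0548 with an estimated correlation, with Spib, a B cell transcription factor gene, at 1.43 and Lck, a T cell kinase gene, at 1.06.

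Of 16 acute phase genes 3 rose at 18 µg, 7 adjusted over the list alone (median 0.67, camera adjusted p 2.59e-07, adjusted p = 0.106 with an estimated correlation). Of 15 genes of cytokines and the inflammasome 2 rose, 8 adjusted over the list alone (median 0.65, camera adjusted p 7.17e-06, adjusted p = 0.102 with an estimated correlation). Particle-laden macrophage and lysosome genes also rose at 18 µg of NRCWE-049, 6 of 24, with Ctsk at 1.06 ± 0.28 and Trem2 at 1.89 ± 0.50, and 16 adjusted over the list alone (median 0.64, adjusted p = 0.0874 with an estimated correlation). Of 26 matrix genes 4 rose, 8 up and 1 down adjusted over the list alone (adjusted p = 0.106 with an estimated correlation), with Eln, the elastin gene, at 1.28 ± 0.31 and Fap, a gene of activated fibroblasts, at 0.70 ± 0.19. Of 16 clock genes Tef and Hlf fell, with 2 up and 6 down adjusted over the list alone and a median of -0.36 (adjusted p = 0.0836 with an estimated correlation). Of 10 alveolar type 1 markers Vegfa fell, by 0.49, with 5 lower adjusted over the list alone (median -0.46, adjusted p = 0.0619 with an estimated correlation). Fat cell markers had a median of 1.01 with none of 7 called (camera adjusted p 0.0363, adjusted p = 0.497 with an estimated correlation), and their scores on single arrays ran from -0.56 to 3.65. In total 548 genes were called, 447 higher and 101 lower. With fry, which does not compare a list with other genes, 16 of the 27 lists were called. On each of the 4 slides that held this group and a control, the medians of the interferon, chemokine and complement lists lay above control, by 1.55 to 2.51, 0.99 to 2.23 and 0.77 to 1.16. Replicate 5 lay alone on its slide, so slide as a fixed block, with 1370 genes called, leaves it out. Slide as a random block gave 894. The count was 291, 14, 212 and 65 without control replicates 1, 3, 4 and 5, 11 without each of exposed replicates 2, 3 and 4, and 1136 without exposed replicate 5. Most remaining calls were then lower without control replicate 3 (10 of 14) and without exposed replicates 2, 3 and 4 (8, 7 and 8 of 11). It was 1185 without the 4 arrays with over 75% of probes above background, and the deposited log ratios gave 68 genes, 45 higher and 23 lower.

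**Figure D3:**
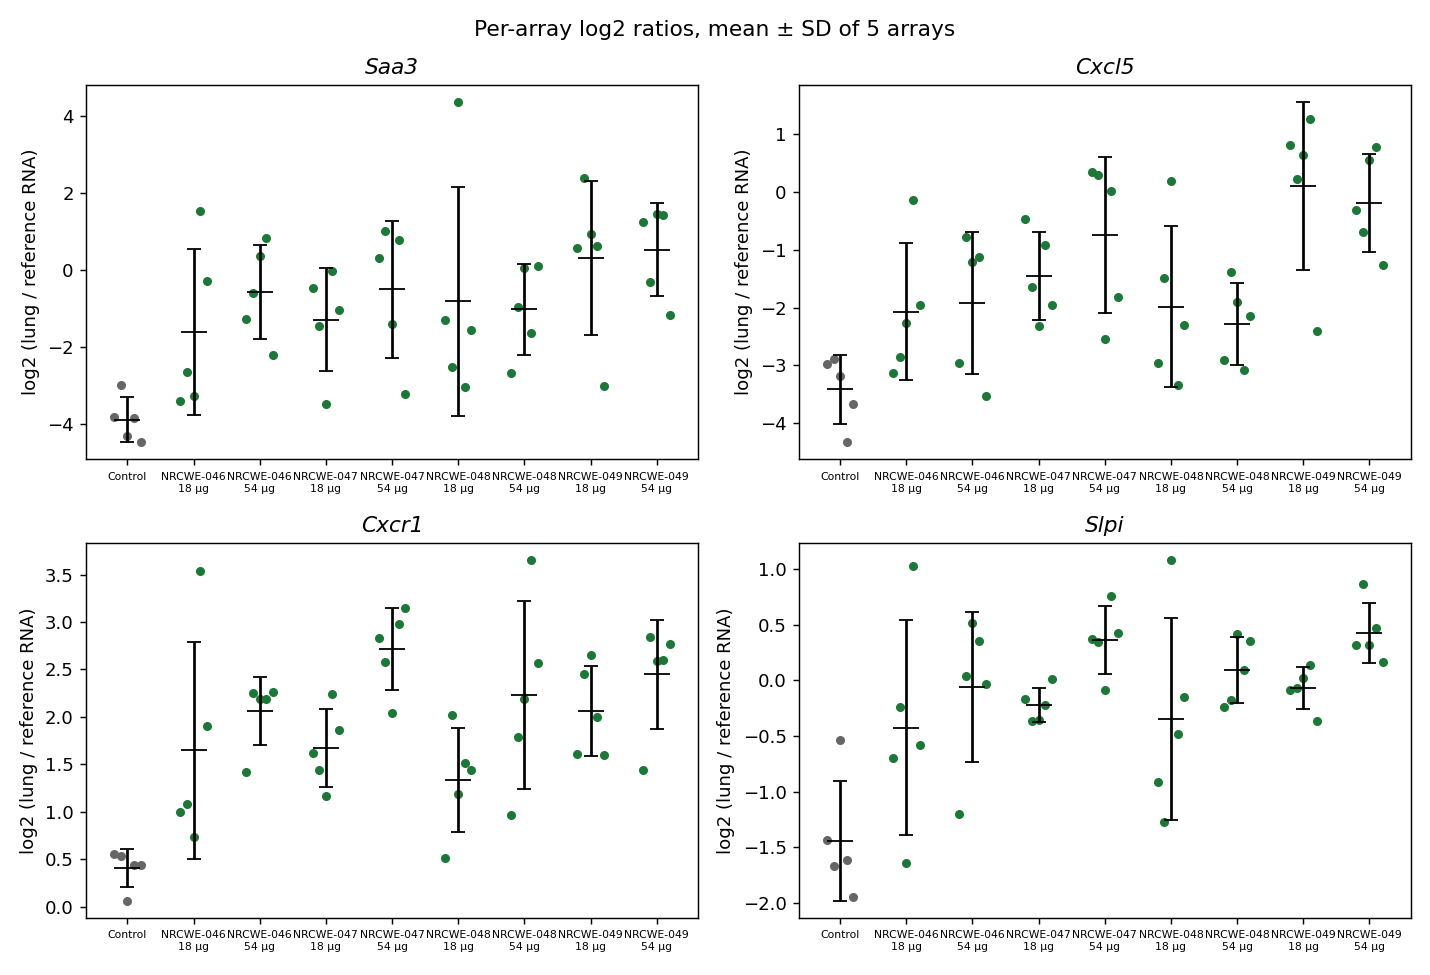
Log2 ratio of lung to reference RNA (vertical axes) for Saa3, Cxcl5, Cxcr1 and Slpi on each array (points) by group (horizontal axes), with the mean and SD of 5 arrays. Cxcl5 in replicate 5 of NRCWE-049 at 18 µg lay at -2.40, while the other 4 arrays of the group lay between 0.22 and 1.27.

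Between the doses of NRCWE-049 no gene passed the test in limma, with 3886 genes at an unadjusted p below 0.05. The smallest adjusted p was 0.0926, shared by Ncapd3, a chromosome condensation gene, at -0.56 ± 0.11, Hmgcs1, an early enzyme gene of cholesterol synthesis, at 0.70 ± 0.14 and Zfp960 at -0.48 ± 0.10. Cholesterol synthesis genes had a median of 0.40 at 54 against 18 µg, with none of 19 called over all genes and 13 higher adjusted over the list alone. Camera gave that list an adjusted p of 5.24e-15, against an adjusted p of 0.12 with an estimated correlation, and fry gave 0.0496. The interferon list had a median of -0.69 (camera adjusted p 0.00333, adjusted p = 0.942 with an estimated correlation), with none called over all genes and 1 lower adjusted over the list alone. Against control, the called genes of both doses shared 212 that rose and 75 that fell, but both doses were set against the same 5 control arrays, which alone makes calls overlap. Independent lists would share 13 and 6.65, values that leave out the shared controls. Without exposed replicate 2 at 54 µg 787 genes were called between the doses, without replicates 1, 3 or 4 the counts were 2, 1 and 2, and without the pair of slides scanned last, which left 2 arrays at 54 µg, 6087.

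At 54 µg of NRCWE-048 more genes rose than fell. Cxcr1, a neutrophil chemokine receptor gene, rose by 1.83 ± 0.39 (adjusted p 0.0195), Slpi, which encodes an inhibitor of neutrophil proteases, by 1.53 ± 0.34, Csf3r, the receptor gene of granulocyte colony-stimulating factor, by 0.93 ± 0.21 and Ctsk, a lysosomal protease gene, by 1.12 ± 0.28. H2-Q4, an MHC class I gene, rose by 1.42 ± 0.35 and the noncoding Fbxl12os by 1.35 ± 0.30. St6galnac1, Mtif2, Dcaf12l2, Ulk3, Tmem255b and Ttc38 rose by 0.85 to 0.96, but the lowest further probe of Dcaf12l2, Ulk3, Tmem255b and Ttc38 was at 0.04, 0.08, -0.19 and -0.16. Angptl4, an inhibitor of lipoprotein lipase, fell by 1.26 ± 0.31 (adjusted p 0.0308), Adamts9, Adamtsl4 and Sema3c, genes of secreted matrix or guidance proteins, by 0.85 ± 0.23, 0.65 ± 0.16 and 0.64 ± 0.17, the heat shock gene Hspb1 by 0.64 ± 0.17, Tcim by 0.63 ± 0.14, and Rtl8b and Rtl8c by 0.67 ± 0.15 and 0.62 ± 0.14. All 20 genes moved the same way on all 5 arrays, as the naming rule required, with Cxcr1 well above background on 1 of 5 controls.

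Of 24 macrophage and lysosome genes at 54 µg of NRCWE-048 only Ctsk rose, with 5 higher adjusted over the list alone (median 0.49, above control on 3 of 4 shared slides, camera adjusted p 1.37e-07, adjusted p = 0.701 with an estimated correlation). Of 14 neutrophil markers 1 rose, also 1 adjusted over the list alone (median 0.24, above control on 3 of 4 shared slides, camera adjusted p 0.0731, adjusted p = 0.701 with an estimated correlation). B cell and plasma cell markers had a median of 0.53 with none of 19 called either way, and lay above control on 4 of 4 shared slides (adjusted p = 0.701 with an estimated correlation). Heart and skeletal muscle markers were lower, with a median of -0.80 and none of 13 called (camera adjusted p 0.0162, adjusted p = 0.701 with an estimated correlation). In total 350 genes were called, 316 higher and 34 lower, 206 of them by at least 1.5-fold. The count was 0, 67, 170 and 67 without control replicates 1, 2, 3 and 4, and 53 and 1 without exposed replicates 1 and 3. It was 655 with only the groups compared in the fit and 803 without the 4 arrays with over 75% of probes above background. The deposited log ratios gave 195 genes, 136 higher and 59 lower, and the Cy5 signal alone gave 0 in limma, with 2269 at an unadjusted p below 0.05.

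At 18 µg of NRCWE-048 no gene passed the test in limma (1102 at an unadjusted p below 0.05, with 1185 by chance). The 3 smallest p values belonged to Rhof, a small GTPase gene, at 0.65 ± 0.16, Map4k1, a kinase gene of lymphocytes, at 0.71 ± 0.19 and Coro1a, an actin-binding gene of leukocytes, at 0.59 ± 0.15, each with an adjusted p of 0.916. Markers of B cells and plasma cells had a median of 0.68, with 8 of 19 higher adjusted over the list alone and none over all genes (camera adjusted p 3.92e-16, adjusted p = 0.161 with an estimated correlation), and lay above control on 2 of 3 shared slides. Control replicate 3 had a B cell score of -0.384, below the other controls at 0.013 to 0.162, which enters every comparison of this list with control. Acute phase genes had a median of 0.52, with 2 of 16 adjusted over the list alone and Lcn2 at 1.22 ± 0.41, but replicate 3 had a score of 2.35 and the other 4 arrays 0.0311 to 0.638. Cholesterol synthesis genes had a median of 0.29, with 3 of 19 adjusted over the list alone. Both lists had an adjusted p of 0.161 with an estimated correlation.

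At 54 µg of NRCWE-047, Cxcr1 rose by 2.31 ± 0.39 (adjusted p 0.0115) and Slpi by 1.80 ± 0.34, Irf5, a transcription factor gene of inflammatory macrophages, by 0.84 ± 0.16 and Cotl1, an actin-binding gene of leukocytes, by 0.85 ± 0.16 (adjusted p 0.0314 for each of the latter 3). Vldlr, which encodes a lipoprotein receptor, fell by 0.54 ± 0.10. Of 24 macrophage and lysosome genes 16 were higher adjusted over the list alone and none over all genes, with Ctsd at 1.28 ± 0.27 (adjusted p 0.0803), Trem2 at 2.03 ± 0.50 and Gpnmb at 2.51 ± 0.66. The list's median was 0.61 (camera adjusted p 1.01e-17, adjusted p = 0.148 with an estimated correlation). Chemokine genes had a median of 0.67, with 9 of 23 adjusted over the list alone and Ccl6 at 1.49 ± 0.30, and cholesterol synthesis genes a median of 0.33, with 5 of 19 adjusted over the list alone and Mvd at 0.83 ± 0.18. Both had an adjusted p of 0.148 with an estimated correlation. Heart and skeletal muscle markers had a median of -0.61 with none of 13 called (camera adjusted p 0.0218, adjusted p = 0.483 with an estimated correlation). In total 6 genes were called, 5 higher and 1 lower. The count was 384 with only the groups compared in the fit, 379 without the 4 arrays with over 75% of probes above background, 207 with scores of other tissue in the fit and 1 with slide as a fixed block. It was 1, 3, 2, 1 and 2 without control replicates 1 to 5, 0, 1, 72, 2 and 0 without exposed replicates 1 to 5, and 9 with the deposited log ratios, 4 higher and 5 lower, and 11 with the scanner software's, 8 higher and 3 lower.

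At 18 µg of NRCWE-047 no gene passed the test in limma, with 1204 at an unadjusted p below 0.05. The 3 smallest p values belonged to Atf5, a stress-response transcription factor gene, at -0.50 ± 0.12, Tnfrsf1b, a TNF receptor gene, at 0.73 ± 0.18 and Hk2, a hexokinase gene, at 0.73 ± 0.19, each with an adjusted p of 0.947. Markers of B cells and plasma cells and of T cells and NK cells had medians of 0.50 and 0.35 with none of 19 and 20 called, over all genes or adjusted over the list alone (camera adjusted p 1.20e-11 for each, adjusted p = 0.154 with an estimated correlation). These were not the only lists to shift, since camera with its preset correlation called 14 of the 27. Mean scores were 0.547 and 0.397 for these B cell and T cell lists. They were 0.767, 0.672, 0.5 and 0.464 for the interferon, chemokine, complement and macrophage and lysosome lists.

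NRCWE-046 gave few calls against control. At 18 µg Thbs1, which encodes thrombospondin, a matrix glycoprotein, rose by 0.96 ± 0.17 (adjusted p 0.00624), the 1 gene with a symbol among 5 that rose (1668 at an unadjusted p below 0.05). At 54 µg the 1 transcript called had no symbol (1787 at an unadjusted p below 0.05). The smallest p of a named gene there was that of Arid5a, an RNA-binding regulator of inflammatory transcripts, at 0.83 ± 0.16 (adjusted p 0.073). Interferon genes at 54 µg had a median of 0.90, with 10 of 20 higher adjusted over the list alone and none over all genes, among them Oas1a at 2.26 ± 0.70 (camera adjusted p 5.70e-14, adjusted p = 0.179 with an estimated correlation). Macrophage and lysosome genes at 54 µg had a median of 0.47, with 7 of 24 higher adjusted over the list alone, Ctsk at 1.00 ± 0.28 and Clec4d at 1.28 ± 0.36. At 18 µg that list had a median of 0.43 with none called, and its scores on single arrays ran from -0.0399 to 1.4. The adjusted p of this list at 54 and 18 µg was 0.179 and 0.816 with an estimated correlation. Chemokine genes at 54 µg had a median of 0.79 with 3 of 23 adjusted over the list alone (adjusted p = 0.179 with an estimated correlation), and fat cell markers 0.75 (adjusted p = 0.547 with an estimated correlation). The fat cell scores of single arrays at 54 µg ran from -0.592 to 3.32. The count at 18 µg was 2, 32 and 10 without exposed replicates 1, 4 and 5 and 3 and 17 without control replicates 2 and 5, and 62 without the 4 arrays with over 75% of probes above background.

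Between the doses of the other materials, 1 gene passed the test. Nr4a1, an early response transcription factor gene, was 1.46 ± 0.25 higher at 54 than at 18 µg of NRCWE-046 (adjusted p 0.0137, higher in 5 of 5 arrays), and was lost without replicates 1, 3 or 4 of either dose. Zbtb16, a glucocorticoid-responsive gene, was at -1.84 ± 0.37 (adjusted p 0.126). The interferon list had a median of 0.94 for NRCWE-046 between the doses, with none of 20 called (camera adjusted p 2.12e-17, adjusted p = 0.638 with an estimated correlation), and at 18 µg replicate 5 scored 1.09 where the other 4 arrays scored -0.321 to -0.0558. For NRCWE-047 limma called no gene (690 at an unadjusted p below 0.05), with Tmem267 at -1.22, Usp17ld at -0.28 and Pde1a at -0.48, and cholesterol synthesis genes had a median of 0.26 with none of 19 called (camera adjusted p 1.99e-14, adjusted p = 0.141 with an estimated correlation). For NRCWE-048 limma also called none (1263 at an unadjusted p below 0.05), 1 without replicate 1 at 18 µg, with Olfr1443 at 0.45, Sox10 at -0.42 and Cd209g at -0.47. Macrophage and lysosome genes had a median of 0.28 there (camera adjusted p 9.53e-05, adjusted p = 0.85 with an estimated correlation). Fat cell markers had medians of -1.24 and -1.1 for NRCWE-047 and NRCWE-048, with adjusted p of 0.755 and 0.85 with an estimated correlation, and replicate 2 of NRCWE-047 at 54 µg scored 0.872 where the other 4 arrays scored -1.24 to -0.769.

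**Figure D4:**
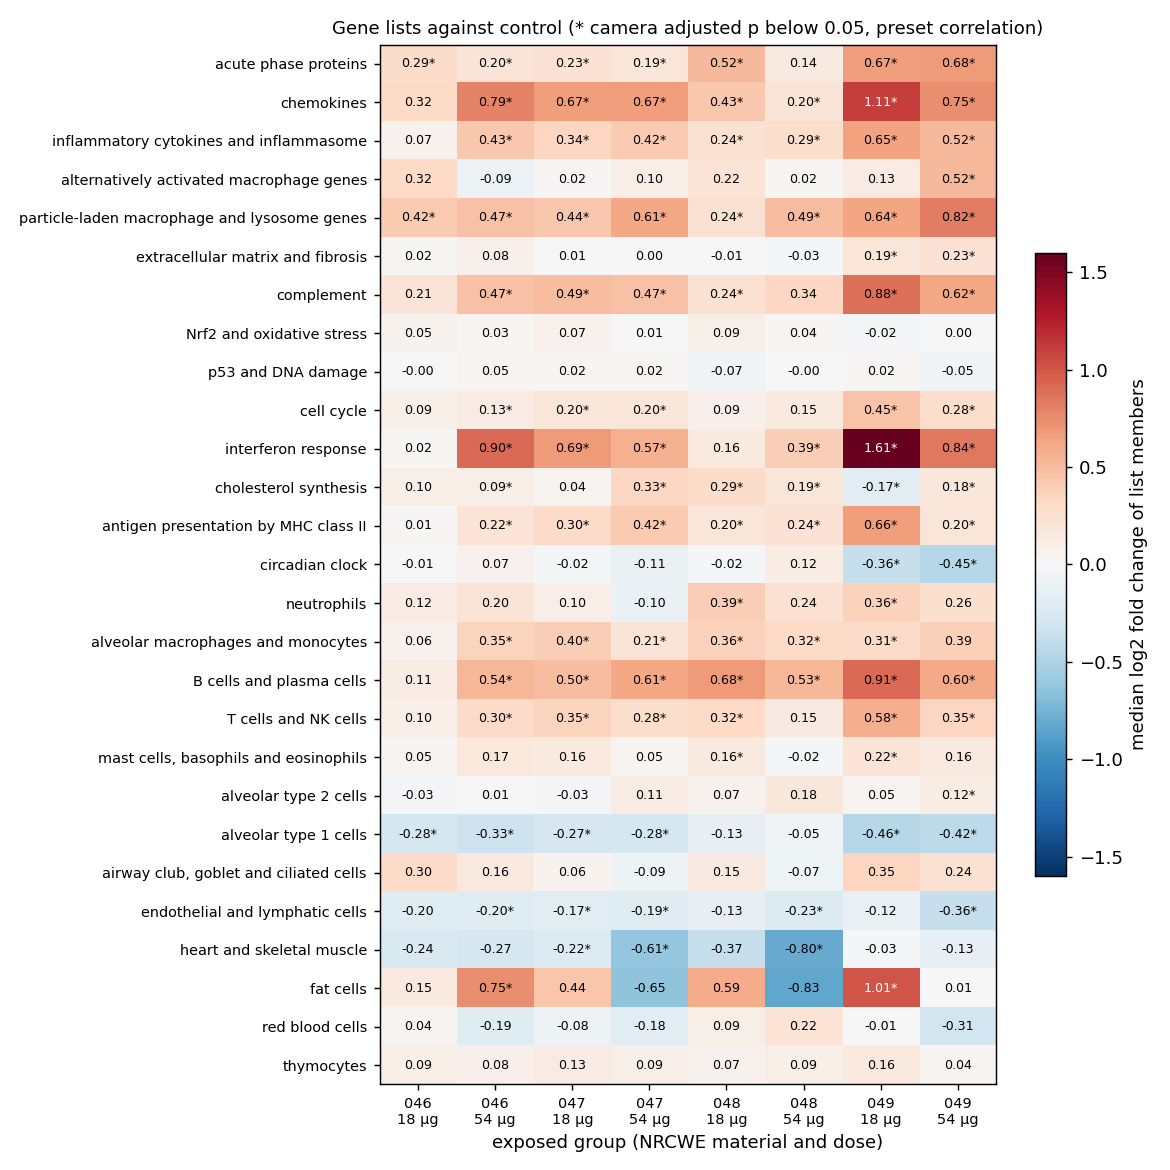
Median log2 change against control (colour and printed value) of the measured genes of each of the 27 lists (vertical axis) for each material and dose (horizontal axis). Stars mark a camera adjusted p below 0.05 with the preset correlation, and none of the starred values passed with an estimated correlation.

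The materials differed from one another at both doses, by a moderated F test over the 4. At 54 µg 1589 genes differed, and the widest range among named genes was that of Spon2, a secreted matrix protein gene, at 1.42, -1.23, -0.60 and -0.27 against control for NRCWE-049, NRCWE-048, NRCWE-047 and NRCWE-046 (adjusted p 5.66e-04). H2-Q4 was at -0.72, 1.42, 0.03 and 0.24 in the same order (adjusted p 7.33e-04), Slc26a1 at -1.5, 0.46, -0.35 and -0.53 (adjusted p 0.00269) and Angptl4 at 0.68, -1.26, -0.85 and -0.08 (adjusted p 3.14e-04). At 18 µg 74 genes differed, with Angptl4 at 0.69, -0.90, -0.36 and 1.04 (adjusted p 0.00266), and 4 interferon-inducible genes, Igtp, Tap1, Ifi47 and Tgtp2, with ranges of 1.45, 1.45, 1.28 and 1.25. The count at 54 µg was 433 on arrays with matching labels, 2974 without the slides scanned last, 1026 without NRCWE-048 replicate 3 and 2591 without NRCWE-049 replicate 2. At 18 µg it was 0 on arrays with matching labels (1607 at an unadjusted p below 0.05 in limma), 300 without the 4 arrays with over 75% of probes above background, 29, 27, 122 and 112 without NRCWE-046 replicates 1 to 4, 35 and 39 without NRCWE-047 replicates 4 and 5, 49 without NRCWE-048 replicate 4, and 46, 47, 43 and 360 without NRCWE-049 replicates 2 to 5.

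Taken in pairs at 54 µg, NRCWE-049 and NRCWE-048 had the most genes called, 354 higher and 2367 lower with NRCWE-049. Spon2 was 2.65 ± 0.44 higher (adjusted p 7.73e-05), Cxcl5 2.09 ± 0.66 higher (adjusted p 0.0324) and Angptl4 1.94 ± 0.31 higher, and H2-Q4 and Slc26a1 were at -2.14 ± 0.35 and -1.96 ± 0.36. The total of 2721 became 1647 without NRCWE-048 replicate 3 and 4109 without NRCWE-049 replicate 2, and with the deposited log ratios it was 1562, 378 higher and 1184 lower. NRCWE-048 differed from NRCWE-047 in 727 genes, 699 of them higher with NRCWE-048, with H2-Q4 at 1.39 ± 0.35, Fbxl12os at 1.35 ± 0.30 and Cebpd, an acute phase transcription factor gene, at -1.16 ± 0.28, while Sfi1 and Ulk3 were at 1.29 and 1.22 with a second probe of each at -0.01 and -0.06. That count was 473 and 135 without NRCWE-048 replicates 1 and 3, 374 and 163 without NRCWE-047 replicates 4 and 5, and 344 with slide as a fixed block. Against NRCWE-046, NRCWE-048 differed in 64 genes, with the heat shock genes Hspa1a and Hsph1 at -1.72 ± 0.37 and -1.35 ± 0.31, the early response genes Csrnp1 and Errfi1 at -1.26 ± 0.25 and -1.18 ± 0.27 and Cebpd at -1.38 ± 0.28. That count was 16, 4 and 34 without NRCWE-048 replicates 1, 3 and 4, 4, 15 and 32 without NRCWE-046 replicates 1, 2 and 5, and 169 with slide as a fixed block, and the deposited log ratios gave 3.

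Between NRCWE-049 and NRCWE-046 at 54 µg limma called 122 genes, 109 of them lower with NRCWE-049, with the clock genes Per1, Hlf and Per2 at -1.65 ± 0.28, -1.40 ± 0.27 and -1.20 ± 0.25 and Setd5 at -1.02 ± 0.11 (adjusted p 7.24e-07). Between NRCWE-049 and NRCWE-047 it called 25, with Spon2 at 2.02 ± 0.44, Angptl4 at 1.53 ± 0.31, Gsta3 at -1.07 ± 0.21, Setd5 at -0.87 ± 0.11 and the cell cycle kinase gene Wee1 at -0.83 ± 0.15. As many genes were called in 15 and 11 of 100 splits of the arrays compared, the real one included, so chance is not excluded for either count. The first count was 34, 16, 302 and 28 without NRCWE-046 replicates 2 to 5, 1206, 74 and 35 without NRCWE-049 replicates 2 to 4, and 2 with slide as a fixed block. Without NRCWE-049 replicate 1 the side changed, with 72 higher and 38 lower. The second was 4, 4, 13, 7 and 16 without NRCWE-047 replicates 1 to 5, 14 (7 higher, 7 lower), 371, 13 and 4 without NRCWE-049 replicates 1 to 4, and 9 with slide as a fixed block. With the deposited log ratios limma called 0 genes for both, with 2985 and 1619 at an unadjusted p below 0.05. Between NRCWE-047 and NRCWE-046 limma called none, with 850 at an unadjusted p below 0.05.

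At 18 µg, NRCWE-049 differed from NRCWE-046 in 228 genes, 126 higher and 102 lower. The interferon-inducible genes Phf11a, Rtp4, Phf11b and Ifit3b were 1.81 ± 0.41, 1.78 ± 0.46, 1.67 ± 0.39 and 1.65 ± 0.43 higher and Myzap 2.15 ± 0.56 higher (adjusted p 0.0455). That count was 8, 4 and 408 without NRCWE-046 replicates 1, 2 and 5, 3, 3, 9 and 656 without NRCWE-049 replicates 2 to 5, and 652 with slide as a fixed block. The side changed without NRCWE-046 replicates 3 (39 higher, 113 lower) and 4 (70 and 116) and without NRCWE-049 replicates 2 (0 and 3), 3 (1 and 2) and 4 (4 and 5). NRCWE-047 differed from NRCWE-046 in 62 genes, 57 of them lower, with Angptl4 at -1.40 ± 0.31 (adjusted p 0.0293), Pign, a gene of lipid anchor synthesis, at -1.08 ± 0.25 and Snap25, a synaptic gene, at -1.01 ± 0.22, while Marchf1 and Ulk3 were at -1.23 and -1.06 with a second probe of each at 0.50 and 0.09. That count was 10, 23, 133 and 98 without NRCWE-046 replicates 1 to 4 and 28, 23 and 25 without NRCWE-047 replicates 1, 4 and 5. NRCWE-048 differed from NRCWE-046 in 4 genes, Angptl4 at -1.94 ± 0.31, Thbs1 at -0.95 ± 0.17, Picalm at -0.53 ± 0.10 and Sgms1 at -0.52 ± 0.10. That count was 2, 2 and 1 without NRCWE-046 replicates 1, 2 and 4 and 1, 7, 1 and 0 without NRCWE-048 replicates 2 to 5, and 0 with the deposited log ratios (limma, 1415 at an unadjusted p below 0.05).

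NRCWE-049 at 18 µg differed from NRCWE-047 in 5 genes, among them Slc25a33, a mitochondrial carrier gene, at -0.75 ± 0.15, Setd5 at -0.73 ± 0.11 (adjusted p 0.00236) and Sema6b at -0.41 ± 0.08. It differed from NRCWE-048 in 13, with Angptl4 at 1.59 ± 0.31, Acot1, a fatty acid metabolism gene, at 1.03 ± 0.22, Mmp2, a matrix protease gene, at 1.02 ± 0.21, Rnd1 at -0.97 ± 0.17 and Rab5c at -0.94 ± 0.19. Against NRCWE-048, 1 of 19 cholesterol synthesis genes was lower, 15 adjusted over the list alone (median -0.49, camera adjusted p 1.84e-20). The adjusted p of 0.032 with an estimated correlation was the only one below 0.05 in any comparison, and fry gave 0.00445. Interferon genes had a median of 1.31 there, with none of 20 called over all genes and all 20 higher adjusted over the list alone (camera adjusted p 3.73e-24, adjusted p = 0.113 with an estimated correlation, fry 0.036). The first count was 3, 1 and 1 without NRCWE-047 replicates 2, 4 and 5 and 2, 8, 2, 2 and 3 without NRCWE-049 replicates 1 to 5, and 0 with the deposited log ratios (limma, 1599 at an unadjusted p below 0.05). The second was 6, 5 and 7 without NRCWE-048 replicates 1, 2 and 4 and 5, 8, 6 and 244 without NRCWE-049 replicates 2 to 5, and of the 13 genes 6 were higher and 7 lower, but without replicate 5 212 were higher and 32 lower. Between NRCWE-048 and NRCWE-047 limma called none, with 1257 at an unadjusted p below 0.05.

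Changes against control were compared across materials, which share the same 5 control arrays. At 54 µg the correlation across genes between materials was 0.39 to 0.777, where the shared controls alone gave 0.506 in simulated data, and 0.25 to 0.583 when the 2 materials were set against different controls. The covariance was 0.0283 to 0.0547, where the shared controls alone gave 0.0138, with 0.39 and 0.0283 the values of NRCWE-048 and NRCWE-049. These correlations are across genes, which are not independent replicates. NRCWE-048 and NRCWE-049 had 22 genes rising in common, 18 falling in common and 6 in opposite directions. Independent lists would share 9.21 and 2.24, a value that leaves out the shared controls, so the excess is no measure of a shared effect. NRCWE-047 shared 4 rising genes with NRCWE-048 and 5 with NRCWE-049, and 1 transcript without a symbol was called with all 4 materials.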

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

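The tests that leave out replicate 1 or another array of NRCWE-049 at 54 µg, that count genes falling in its other 4 arrays, that ask about slides and that use scores of other tissue were chosen only after the data were seen, and the other tests here were planned.

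Within groups of 5 arrays, 16 values of 360 sets stood apart from the other 4, which is 4.44% where chance gives about 5%. In replicate 1 of NRCWE-049 at 54 µg the mean marker scores were -1.57 for endothelial and lymphatic cells, -1.11 for alveolar type 1 cells and -0.475 for alveolar type 2 cells, all below the other arrays. Replicate 4 of NRCWE-046 at 18 µg had an endothelial score of -0.412, and replicate 5 of that group an interferon score of 1.09, above the others. Replicate 3 of NRCWE-048 at 18 µg had an acute phase score of 2.35, replicate 4 of NRCWE-048 at 54 µg a matrix score of -0.264 and replicate 1 of NRCWE-046 at 54 µg an Nrf2 score of 0.195. Control replicate 3 had a B cell score of -0.384 and replicate 2 of NRCWE-047 at 54 µg a fat cell score of 0.872. Replicate 1 of NRCWE-048 at 54 µg had 49% of probes well above background, while the others of its group had 56.6% to 58.3%.

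Single genes stood apart as log2 ratios to the reference RNA. In replicate 5 of NRCWE-049 at 18 µg Ly6i was at 1.17 and Cxcl5 at -2.40, both below the other arrays of the group. Control replicate 3 had Cxcr1 at 0.0645, below the other controls, and control replicate 2 had Ly6f at 0.93, above them. Slc26a1 was at 1.30 in replicate 2 of NRCWE-049 at 54 µg, above the others.

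The materials differed from each other by the moderated F test in 74 genes at 18 µg and 1589 at 54 µg. Among 100 splits of the arrays of the 4 materials, the real one included, 2 reached 74 at 18 µg (highest other 150) and 1 reached 1589 at 54 µg (highest other 1154). Few splits gave as many at either dose, but many counts were tested by splits and no correction was made for that.

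Against control, 6 of the counts were reached by few splits, again without a correction for the many counts tested. For 54 µg of NRCWE-049 (2251 genes), 18 µg of NRCWE-049 (548), 54 µg of NRCWE-048 (350) and 54 µg of NRCWE-047 (6), 1 of 100 splits, the real one, gave as many, with highest others of 2136, 450, 54 and 1. For 54 µg of NRCWE-046 the 1 gene called was reached by 1 split (highest other 0), and for 18 µg of NRCWE-046 the 5 genes were reached by 3 (highest other 6). For 18 µg of NRCWE-047 and of NRCWE-048 limma called 0 genes, with 1204 and 1102 at an unadjusted p below 0.05, and since any split calls at least 0, the 100 of 100 splits that did so (highest others 1 and 2) test nothing. Between the doses, the 1 gene of NRCWE-046 was reached by 2 of 100 splits (highest other 4), and without such a correction chance is not excluded. For NRCWE-047, NRCWE-048 and NRCWE-049 limma called 0, with 690, 1263 and 3886 at an unadjusted p below 0.05, and the 100 of 100 splits with at least 0 (highest others 0, 1 and 394) again test nothing. A split of the NRCWE-049 arrays called 394 genes where the doses called none, while the median of the splits was 0, and the reason was not tested.

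Most genes called at 54 µg of NRCWE-049 fell, 1560 of 2251. Of these, 940 were no longer called without replicate 1, and 32, 337, 530 and 56 without replicates 2 to 5. With replicates 2 to 5 each left out in turn, falling calls stayed the larger share. Then 2534, 1474, 1094 and 2259 fell and 1197, 402, 266 and 836 rose. Without replicate 1, 688 fell and 1154 rose. Of the 5 arrays of the group, only replicate 1, when left out, turned the larger share to rising genes. Whether 1 array fewer, whichever it is, costs as many falling calls was not decided, since replicate 4 cost 530 against 940. How many of the 940 were lost only because 1 array was missing cannot be told apart. The 688 genes that fell in the other 4 arrays were matched by 1 of 100 splits of those arrays and the controls, the real one (highest other 274), a test that replaced an earlier one that could not decide. Without replicate 1, 620 of the 1560 and 514 of the 691 rising genes were still called, and 640 more rose. An effect of exposure may account for the falling genes that stayed, but 3 of the 4 arrays lay on slides tied to control only through other exposed groups. With slide as a block 12 of the 688 were still called, at a median of -0.33 with an SE of 0.13 where it had been -0.44 with 0.12, so slide and exposure cannot be told apart for them.

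Immune genes rose at 18 µg of NRCWE-049, among 447 rising genes. Wrong materials in the titles as a whole were argued against by the 23 arrays with conflicting labels. There limma's F test called 0 genes by the treatment field and 10 by the title, a value that just reached the bound set for it. That test pooled the doses and did not ask which genes differed, so it does not address the immune genes at 18 µg by themselves. Heart and muscle, fat or airway tissue carried over with the lung was argued against by the median rise. It was 0.93 with scores for these tissues in the fit and 0.99 without them. Scores of other kinds of tissue were not fitted, so those stay open. For replicates 1 to 4, a difference between slides was argued against by the medians of the interferon, chemokine and complement lists. These lay above control by at least 1.55, 0.99 and 0.77 on all 4 slides shared with a control. With slide as a block 446 of the 447 genes were called, but that fit drops replicate 5. Leaving out replicate 5 alone, without a block, already raised the calls from 548 to 1136, so the 446 do not test slide. An effect of the exposure may account for the pattern as a hypothesis, while different shares of immune cells in the sections, the slide of replicate 5, which lay alone on it and so drops out of that fit, and the 11 genes left without any of replicates 2, 3 or 4 stay open.

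Clock genes fell at 54 µg of NRCWE-049, 7 of 16. In the fit without a slide block, replicate 1 as the source was argued against by 5 of the 7 being called without it. A shift in the time of day at which lungs were taken may also account for the pattern, since Arntl, Npas2 and Clock, which run opposite to the genes that fell, were at 0.61, 0.21 and -0.30 with a median of 0.21, too small to decide, and the labels give no time of day. Arntl and Dbp were at 1.29 and -2.06 at 18 µg of NRCWE-049 and at -0.97 and 1.54 at 54 µg of NRCWE-048, none of them called, so time of day and exposure cannot be told apart here. Slide cannot be told apart either, since with slide as a block 3 of the 7 were called, at a median of -0.80 where it had been -0.99. With that block and without replicate 1, 0 of the 7 were called, at a median of -0.45, so with the block the part of replicate 1 stays open too. The list's median lay below control on both shared slides, at -0.88 and -0.41, but 1 of these slides was that of replicate 1.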

How the results depend on the processing

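The fits without arrays with many probes above background, with their share as a covariate, without replicate 1 of NRCWE-049 at 54 µg and with scores of other tissue were chosen after the data were seen, and the others were planned. Signal over background limits what can be seen, since down to 44.3% of probes lay well above background on an array. The 75% limit was set after the values were seen, and replicate 2 of NRCWE-049 at 54 µg lay just under it at 74.1%. The labels number the samples through the whole series and pair none of them, so arrays were matched only by slide, as a block and on slides shared with a control. The cause was not tested for any of the values that follow, except that a fold limit can only lower a count. Fits on fewer arrays gave lower counts in some comparisons and higher counts in others.

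The 5 genes of NRCWE-046 at 18 µg became 3 with the software's log ratio, 1 with Cy5 alone, 2 with the deposited values, 12 and 21 with slide as a fixed and a random block, 0 on arrays with matching labels, 1 with only the groups compared, 62 without the 4 arrays with over 75% of probes above background, 61 with that share as a covariate, 30 without replicate 1 of NRCWE-049 at 54 µg and 11 with the tissue scores. Leaving out single arrays gave 2 to 32. The 1 gene of NRCWE-046 at 54 µg became 5 with the software's log ratio, 2 with slide as a random block, 21 with only the groups compared, 5 without replicate 1 of NRCWE-049 and 11 with tissue scores, and 1 without any single array. For NRCWE-047 and NRCWE-048 at 18 µg every setting gave 0, single arrays included.

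The 6 genes of NRCWE-047 at 54 µg became 11 with the software's log ratio, 21 with Cy5 alone, 1 and 39 with slide as a fixed and random block, 0 without the slides scanned last, 3 on arrays with matching labels, 384 with only the groups compared, 379 without the 4 arrays, 10 with the covariate, 54 without replicate 1 of NRCWE-049 and 207 with tissue scores. Single arrays gave 0 to 72. The 350 of NRCWE-048 at 54 µg became 0 with Cy5 alone, 195 with the deposited values, 565 with slide as a random block, 0 with matching labels, 206 with a 1.5-fold limit, 655 with only the groups compared, 803 without the 4 arrays, 656 without replicate 1 of NRCWE-049 and 543 with tissue scores. Single arrays gave 0 to 468, and 69.7% rose with the deposited values where 90.3% rose before.

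The 548 of NRCWE-049 at 18 µg became 358 with Cy5 alone, 68 with the deposited values (66.2% rising against 81.6%), 361 without the filter, 1370 and 894 with slide as a fixed and random block, 0 with matching labels, 1185 without the 4 arrays and 990 without replicate 1 at 54 µg. Single arrays gave 11 to 1136. The 2251 of NRCWE-049 at 54 µg became 43 with the deposited values (62.8% rising against 30.7%), 6100 without the slides scanned last, which left 2 arrays (14.5% rising), 1349 with matching labels (69.8% rising), 787 with a 1.5-fold limit, 91 with only the groups compared (58.2% rising), 1344 with the covariate (41% rising) and 3808 with tissue scores. Single arrays gave 799 to 3731.

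Between doses, the 1 gene of NRCWE-046 became 0 with the software's log ratio, the deposited values, slide as a fixed block, matching labels and without the 4 arrays, and 2 with Cy5 alone, slide as a random block, only the groups compared and tissue scores. Single arrays gave 0 to 1. NRCWE-047 gave 0 throughout and NRCWE-048 0 to 1 over single arrays. NRCWE-049 gave 6087 without the slides scanned last, 2 without replicate 1 at 54 µg and 0 to 787 over single arrays. The 74 genes of the F test at 18 µg became 39 with Cy5 alone, 155 and 113 with slide as a fixed and random block, 155 without the slides scanned last, 0 with matching labels, 13 with only the groups compared, 300 without the 4 arrays, 175 with the covariate, 234 without replicate 1 of NRCWE-049 and 245 with tissue scores, and single arrays gave 27 to 360. The 1589 at 54 µg became 795 with the deposited values, 2974 without the slides scanned last, 433 with matching labels, 916 with a 1.5-fold limit and 846 with only the groups compared, and single arrays gave 1026 to 2591.

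Reversals were few. Scgb1a1 at 54 µg of NRCWE-049 turned to 5.05e-04 with Cy5 alone. With the deposited values the fat cell list of NRCWE-046 at 54 µg turned to -0.103 and the heart and muscle list of NRCWE-047 at 18 µg to 0.196. With matching labels 7 lists turned, at 54 µg of NRCWE-046 cell cycle to -0.0842, cholesterol synthesis to 0.0313 and endothelial cells to 0.0507, fat cells at 18 µg of NRCWE-049 to -0.314, endothelial cells at 54 µg of NRCWE-049 to 0.0706, macrophage and lysosome genes between doses of NRCWE-048 to -0.105 and interferon genes between doses of NRCWE-049 to 0.416. With tissue scores heart and muscle turned to 0.0304 and 0.0773 at 18 and 54 µg of NRCWE-047, and fat cells between its doses to 0.084, which follows by construction because the scores of these lists were the covariates.

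Of 217 named gene results, 211 held without background subtraction, 169 with the software's log ratio, 133 with Cy5 alone, 56 with the deposited values, 167 without the filter, 199 with averaged probes, 165 and 211 with slide as a fixed and random block, 155 without the slides scanned last, 61 with matching labels and 120 with only the groups compared. After the added settings 185 to 197 held, and of 2170 results without 1 array 1340 held. The named gene results include genes named by their smallest p that were not called. These count as held when they stay uncalled, which raises each of these counts. Of 125 list results called by camera against control and between doses, 0 held with an estimated correlation and 25 with fry, 104 with the deposited values, 84 with matching labels and 109 to 125 in the other settings.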

Other observations

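The comparison of all exposed arrays together was added after the data were seen, and the genes named from it were chosen after their values were seen, while the lists and the pairs of materials were planned.

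Cell cycle genes were higher at 18 µg of NRCWE-049, where Birc5, a mitosis gene, rose by 1.07 ± 0.29 and 10 of 22 were higher adjusted over the list alone (median 0.45, camera adjusted p 4.34e-10, adjusted p = 0.106 with an estimated correlation). Of 11 genes of antigen presentation by MHC class II, Cd74, the invariant chain gene, rose by 0.71 ± 0.19 at 18 µg and by 0.79 ± 0.19 at 54 µg of NRCWE-049, with 6 higher and with 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.102 and 0.364 with an estimated correlation). At 54 µg the list's median was 0.20, and 0.68 without replicate 1. Of 12 genes of alternatively activated macrophages, Clec10a, a macrophage lectin gene, rose by 1.09 ± 0.31 at 18 µg of NRCWE-049, with 2 adjusted over the list alone, and at 54 µg the list had a median of 0.52 with none called (adjusted p = 0.602 and 0.364 with an estimated correlation). Of 12 alveolar type 2 markers 2 rose at 54 µg of NRCWE-049, Lamp3 at 0.58 and Abca3 at 0.35, also 2 adjusted over the list alone (median 0.12, adjusted p = 0.364 with an estimated correlation), and without replicate 1 the median was 0.32. Of 13 markers of alveolar macrophages and monocytes 3 rose at 18 µg of NRCWE-049, 4 adjusted over the list alone (median 0.31, adjusted p = 0.185 with an estimated correlation).

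Of 14 neutrophil markers none rose and 1 was higher adjusted over the list alone at 18 µg of NRCWE-049 (median 0.36, camera adjusted p 0.013, adjusted p = 0.218 with an estimated correlation), and of 9 markers of mast cells, basophils and eosinophils 2 rose, 3 adjusted over the list alone (median 0.22, camera adjusted p 0.013, adjusted p = 0.106 with an estimated correlation). The lists of Nrf2 and oxidative stress, p53 and DNA damage, airway cells, red blood cells and thymocytes were called by camera in none of the 8 comparisons with control. Their medians ran from -0.02 to 0.09, -0.07 to 0.05, -0.09 to 0.35, -0.31 to 0.22 and 0.04 to 0.16. Bbc3, a p53 target gene of cell death, fell by 0.40 ± 0.12 at 54 µg of NRCWE-049. Foxp3, the regulatory T cell gene, was at least 1.87-fold higher at 54 µg of NRCWE-049 (adjusted p 0.0103), and Prg2, an eosinophil granule gene, at least 1.73-fold higher at 18 µg (adjusted p 0.0495).

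All 40 exposed arrays together against the 5 controls gave 2 called genes, Slpi at 1.41 (adjusted p 0.0371, above the control mean on 39 of 40 arrays) and a transcript without a symbol, with 2288 genes at an unadjusted p below 0.05. As many were reached by 4 of 100 splits, with a highest other of 1179. With many counts tested and no correction for that, chance is not excluded. The median of the splits was 0, and why 1 split called 1179 was not tested. Cxcr1 at 1.62 and Cotl1 at 0.69 lay above the control mean on all 40 arrays (adjusted p 0.0607 each) without passing the test. Aqp1, a water channel gene of endothelium, was at -0.47 and lay below it on all 40 (adjusted p 0.0883).

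Splits of the arrays of each pair of materials gave the following. At 54 µg, NRCWE-049 against NRCWE-048 (2721 genes) was reached by 2 of 100 splits (highest other 3216), NRCWE-048 against NRCWE-047 (727) by 1 (highest other 73) and NRCWE-048 against NRCWE-046 (64) by 1 (highest other 0). These were few splits in each case, but no correction was made for the many counts tested. NRCWE-049 against NRCWE-046 (122) was reached by 15 (highest other 3190) and against NRCWE-047 (25) by 11 (highest other 1115), so chance cannot be excluded. The median of the splits was 0, and the reason for these highest counts was not tested. For NRCWE-047 against NRCWE-046 limma called 0, with 850 at an unadjusted p below 0.05, so the 100 of 100 splits with at least 0 (highest other 1) test nothing. At 18 µg, NRCWE-047 against NRCWE-046 (62) was reached by 1 (highest other 4), NRCWE-049 against NRCWE-046 (228) by 3 (highest other 457), NRCWE-049 against NRCWE-047 (5) by 3 (highest other 516), NRCWE-049 against NRCWE-048 (13) by 2 (highest other 39) and NRCWE-048 against NRCWE-046 (4) by 4 (highest other 73). Few splits gave as many in each case, but without a correction for the many counts tested chance is not excluded. Why splits called 73 and 516 genes where the materials called 4 and 5 was likewise not tested. For NRCWE-048 against NRCWE-047 limma called 0, with 1257 at an unadjusted p below 0.05, so the 100 of 100 splits with at least 0 (highest other 2) test nothing.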
